A study of Mus musculus with 11 samples.

How the data were processed

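RNA from Neuro-2A (N2A) mouse neuroblastoma cells was collected 48 h after transfection with siRNA pools against Fubp1, Khsrp, Khsrp and Fubp1 together, or Rbm38 (2 libraries each), or with non-targeting pools (siNT, 3 libraries). Stranded libraries of polyadenylated RNA had been prepared with a protocol adapted for longer inserts. Groups and replicate letters were taken from the sample descriptions, since the titles of both Fubp1 libraries end in the letter A while their descriptions give A and B. The replicate letters do not pair samples across groups, as A minus B differences correlated between -0.062 and 0.058 across events, so no pairing was used in the comparisons. No 2 libraries were duplicates of each other.

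The authors deposited an expression table with a single RPKM value per group for 52661 genes and, for 23378 genes, the authors' log2 fold change, p-value and adjusted p-value (FDR) of each knockdown against siNT. The submitters' notes name the mouse build mm10, Salmon 0.14.1 and edgeR without a version. How the replicates were combined is not given in the sources used here. Expression values per library were not given in the sources used here. The planned edgeR or limma fits of expression, the comparison of the double with the single knockdowns, the interaction in expression, set tests with an estimated correlation, fry, and fits without 1 library could therefore not be run for expression. The authors' values are reported as they stand. Neither an error nor a number of replicates can be given for a gene's level. The authors' adjusted p-values differed from a Benjamini-Hochberg adjustment of their p-values by up to 2.10e-04.

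Splicing came as a table in the layout of vast-tools (version not given in the sources used here) with 401633 entries for 358106 events. For each library it holds percent spliced in (PSI, in percent, as deposited by the authors) and a quality text with corrected inclusion and exclusion reads. PSI recomputed from these reads differed from the deposited percent by up to 0.05 points. A further table by the authors gives a PSI score per group and a True or False call of each event and knockdown, by a criterion not given in the sources used here. It marks none of the tested alternative 3′ or 5′ splice sites. The coordinates of the event table do not follow GRCm38. Of 355064 events whose gene name is in GENCODE vM21, 12.0% lay within that gene. The build is not given in the sources used here, and coordinates are printed as deposited. Of 63 named exons, 56 were matched to the GENCODE annotation by the length of a flanking intron and 45 were coding. No genome sequence was used, so no sequence motif was examined.

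Of the listed entries 37194 that stand for the first site of a group of alternative splice sites were left out, 220976 events had at least 10 reads in every library, and the 60137 of these with a mean PSI from 1 to 99 were tested, in 9317 genes. They comprised 20841 cassette exons, 478 microexons (up to 27 nt), 26596 retained introns, 7031 alternative 3′ and 5191 alternative 5′ splice sites. The log2 ratio of inclusion to exclusion reads, with 0.5 added to each, was fitted in limma with 1 mean per group over all 11 libraries and empirical Bayes moderation with a trend. The 8 comparisons were the 4 knockdowns against siNT, the double against each single knockdown, the double against the sum of both single effects, and Khsrp against Fubp1 knockdown. An event was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison and a difference of mean PSI of at least 10 points. Differences between replicates exceeded counting error in 16.8% to 28.0% of events, depending on the pair of libraries. Reads carry no molecular identifiers, so read numbers cover counting error only.

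The test was checked on simulated reads at the depth of the real libraries, with 100 events changed by 15 and 100 by 30 points in each knockdown and a library SD of 0.22 on the log2 odds. That SD is a floor set for the simulation, not an estimate. The unweighted fit recovered 5 to 10 of 100 changes of 30 points and 0 to 3 of 100 changes of 15 points, with 0 false calls. With weights from the binomial variance of the log odds, a fit set out beforehand, it recovered 84 to 91 of 100 and 39 to 50 of 100. Of its calls 4.9% to 11.2% were false. Recovery and the share of false calls depend on how many events change. So few of the 60137 were changed here that these are not the rates in the real data. Both counts and the authors' calls are therefore printed together. In 100 simulated runs with independent genes cameraPR called a list shifted by 1 SD every time and 3 of 2000 other lists. Lists of correlated genes were not simulated, so this does not check false calls for them.

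Gene lists were tested with cameraPR (preset correlation 0.01) on z values made from the authors' p-values and the signs of their log2 fold changes, adjusted over 88 tests of 22 lists in 4 knockdowns. The lists were targets and paralogs, neuronal differentiation, neural progenitor, sympathoadrenal and proneural transcription factors, splicing regulators, p53 targets, S phase, G2 and M phase, MYC targets, immediate early and AU-rich element mRNAs, let-7 targets, interferon-stimulated genes, integrated stress and unfolded protein response, cholesterol, hypoxia and glycolysis, extracellular matrix and adhesion, axon guidance, mesenchymal, astrocyte, oligodendrocyte and Schwann cell, microglia and leukocyte, and endothelial markers. Member counts use the authors' FDR under 0.05, and those adjusted over the list alone use their p-values. Calls by event class and the link of expression with splicing were tested with Fisher's exact test and exact binomial tests, two-sided, adjusted over 32 class tests and over the knockdowns. Overlaps were set against the number expected for independent calls and against groups simulated without change that share the 3 controls. For expression that simulation took each gene's standard error from the authors' p-value by a normal quantile.

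Lists, comparisons, thresholds, the other settings listed last and the rule for named items were fixed before the data were examined. The rule named the 10 highest and 10 lowest log2 fold changes per knockdown among genes at the authors' FDR under 0.05 and a mean of at least 1 RPKM (leaving out symbols of the form Gm plus digits or ending in Rik), the targets and paralogs, and up to 4 members per list with the smallest p. Its demand that libraries of both groups not overlap could not be applied to genes. For splicing it named, per knockdown, 5 exons each way, 3 introns, 2 alternative splice sites and 4 events of a preset list of genes with the largest PSI difference or, for the preset list, the smallest p, among called events with no overlap between the groups' libraries, and 3 events each way for the other comparisons (1 higher for the interaction). The text gives examples of these. Called events met that condition in every comparison except for 2 of the 3168 in the double knockdown. Chosen after the data were seen were the term for library sets numbered 1 to 4 and 8 to 27 (alone and with weights), the restriction to introns with balanced junction reads, a filter at 1 RPKM, ranks or log2 fold changes as the list statistic, the tests of microexons as a set, the range of 20 to 80% in siNT for the direction of called exons, and the exons named for Khsrp and in part for Rbm38. The settings set out beforehand were 20 or 50 reads as the minimum, no PSI difference or 15 points, 2 added to reads, no PSI filter, the vast-tools coverage score, the replicate letter as a term, only the groups compared, leaving out each library, an absolute log2 fold change of at least 1, and a filter at 5 RPKM, applied to group values.

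R 4.3.3, limma 3.58.1, data.table (1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.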

Results

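Messenger RNA was sequenced from 11 libraries of Neuro-2A (N2A) cells, a mouse neuroblastoma line, 48 h after transfection with pools of small interfering RNAs. The pools targeted Fubp1 (2 libraries), Khsrp (2 libraries), both genes together (2 libraries, called the double knockdown here), Rbm38 (2 libraries), or no gene (siNT, 3 control libraries). Fubp1 and Khsrp encode RNA-binding proteins with KH domains, and Rbm38 encodes an RNA-binding protein with an RNA recognition motif that is also a target of p53. The series describes the targets as splicing factors, and the comparisons ask how splicing and transcript levels differed after their knockdown. Splicing was read as percent spliced in (PSI), the share of transcripts that include an exon, keep an intron or use a splice site. The median read number per tested event was 171, 221 and 141 in siNT A, B and C, 195 and 168 in the Fubp1 knockdown, 183 and 113 in the Khsrp knockdown, 133 and 99 in the double knockdown, and 167 and 166 in the Rbm38 knockdown. Total reads per library were not given in the sources used here. Expression came as 1 value per group in the authors' deposited table, so gene levels carry no error here, and differences of expression rest on the authors' own test.

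Each targeted transcript was lower in its own knockdown. In the authors' deposited table, Fubp1 (ENSMUSG00000028034.15) went from 180.07 RPKM in siNT to 27.89 RPKM in its knockdown and 19.82 RPKM in the double knockdown, a log2 fold change of -2.60 (FDR 8.76e-46) and -3.04 (FDR 5.12e-60). Khsrp (ENSMUSG00000007670.9) went from 47.03 RPKM to 8.06 and 6.77 RPKM in the same table by the authors, with log2 fold changes of -2.77 (FDR 3.26e-23) and -2.94 (FDR 7.99e-27). Rbm38 (ENSMUSG00000027510.17) went from 34.47 to 4.03 RPKM, a deposited log2 fold change of -3.42 with the authors' FDR of 2.38e-10. Khsrp also fell in the Rbm38 knockdown, to 33.8 RPKM, by the authors' log2 fold change of -0.70 (FDR 0.0243). The paralog Fubp3 did not pass the authors' test in any knockdown, with log2 fold changes between -0.30 and 0.22, and the deposited table lists Rbm24, the paralog of Rbm38, at 0 RPKM.

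**Figure D1:**
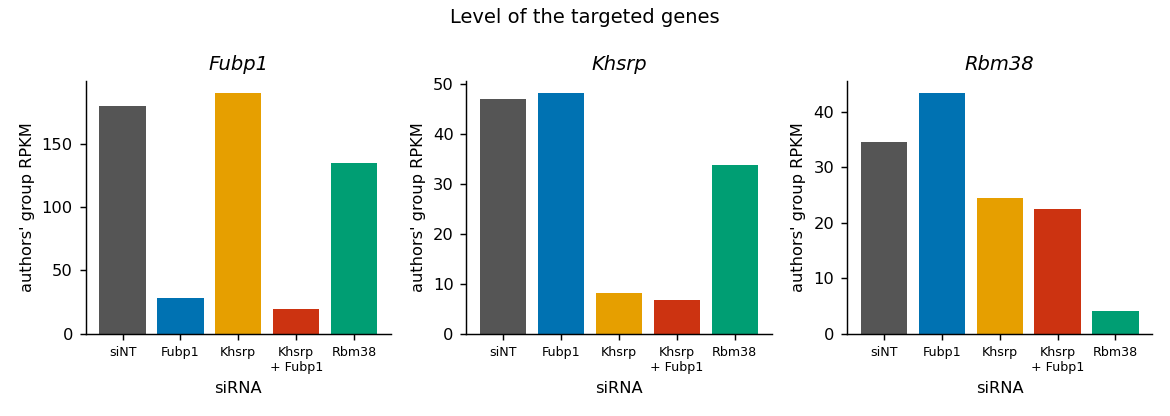
Bars give the authors' deposited level of Fubp1, Khsrp and Rbm38 (RPKM, vertical axis) in the 5 groups, 1 value per group without an error. Fubp1 stood at 180.07 RPKM in siNT and 27.89 RPKM in its own knockdown, Khsrp at 47.03 and 8.06 RPKM, and Rbm38 at 34.47 and 4.03 RPKM.

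Principal component 1 of the log odds of inclusion carried 30% of the variance and set the double knockdown (279.8 and 287.9) apart from the other 9 libraries (-133.7 to 52.7). Component 2 carried 11.6% and followed the library numbers in the titles. Libraries numbered 1 to 4, which are siNT A and B and both Fubp1 libraries, lay between -149.8 and -87.3, and those numbered 8 to 27, which hold siNT C and the other 3 knockdowns, lay between 26.1 and 116.1. A term for these library sets was therefore fitted as an alternative, and its values stand beside the splicing results. The authors' expression comparisons could not be adjusted for it.

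**Figure D2:**
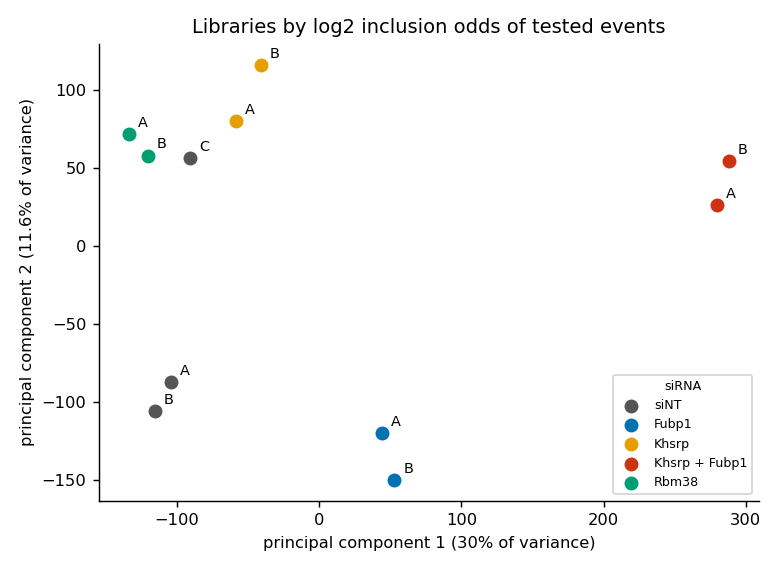
Each point is 1 of the 11 libraries on principal component 1 (horizontal, 30% of the variance) and 2 (vertical, 11.6%) of the log2 odds of inclusion, coloured by group. Both double knockdown libraries lie at 279.8 and 287.9 on component 1, and component 2 parts the libraries numbered 1 to 4 from the rest.

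Genes of S phase, of mitosis and of the integrated stress response were lower after Fubp1 knockdown. Among S phase genes, 38 of 47 fell and none rose (40 adjusted over the list alone). They included Rrm2, a subunit of ribonucleotide reductase, Tyms, the thymidylate synthase, and Dtl. Tyms went from 97.39 to 45.49 RPKM in the authors' deposited table. Among G2 and M phase genes, 41 of 50 fell and none rose (46 adjusted over the list alone). These included the spindle checkpoint kinase Bub1 (69.18 to 32.71 RPKM by the authors' values), the kinetochore protein Nuf2, the condensin subunit Smc4 and the cytokinesis factor Ect2. In the list of the integrated stress and unfolded protein response, 28 of 42 fell and 1 rose (33 and 1 adjusted over the list alone). Its members Cth, which makes cysteine, the cystine transporter Slc7a11, the serine synthesis enzyme Psat1 and the cationic amino acid transporter Slc7a3 had authors' log2 fold changes of -2.25, -1.91, -1.24 and -1.48. With cameraPR from limma on the authors' p-values, the adjusted p was 1.47e-21 for the S phase list, 3.36e-22 for the G2 and M list and 1.09e-16 for the stress list. All 3 also passed with log2 fold changes as the statistic (8.29e-03, 8.29e-03 and 4.32e-03).

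Interferon-stimulated genes went the other way in the Fubp1 knockdown, with 19 of 40 higher and 3 lower (22 and 4 adjusted over the list alone, adjusted p 6.79e-08). They included Dtx3l (2.68 to 9.03 RPKM in the authors' table), the RNA sensor gene Ddx58 (0.67 to 2.71 RPKM), the immunity-related GTPase Igtp and Parp9. MYC targets were lower in 22 of 41 and higher in 1 (23 and 2 adjusted over the list alone, adjusted p 1.40e-06), with the nucleolar genes Npm1 (4114.3 to 2371.04 RPKM by the authors' values), Nop56 and Ncl. Genes of cholesterol synthesis and uptake were lower in 12 of 25 and higher in none (14 adjusted over the list alone, adjusted p 6.34e-07), among them Lss, Insig1 and Stard4. Splicing regulators were lower in 23 of 82 and higher in 7 (29 and 8 adjusted over the list alone, adjusted p 3.43e-03). Rbfox1, a neuronal splicing factor, stood at 4.54 RPKM in siNT and 1.06 RPKM after knockdown in the authors' table. Hypoxia and glycolysis genes were lower in 13 of 34 and higher in 5 (the same 13 and 5 counts adjusted over the list alone, adjusted p 4.86e-03). Axon guidance genes were higher in 16 of 54 and lower in 1 (17 and 1 adjusted over the list alone, adjusted p 7.04e-03), led by Sema6c, Unc5c, Plxna4 and Sema6a. With log2 fold changes as the statistic the adjusted p was 0.333 for MYC targets and for cholesterol genes, 0.377 for hypoxia genes, and 0.753 for splicing regulators and for axon guidance, where ranks gave 0.132.

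Among single genes after Fubp1 knockdown, Myl9 rose and Ctla2a fell by large amounts. In the authors' deposited table, Myl9, a regulatory light chain of myosin, stood at 4.71 RPKM in siNT and 42.29 RPKM after knockdown (log2 fold change 3.28, FDR 4.93e-90), and Acta1, the skeletal muscle actin, at 0.15 and 2.18 RPKM (3.96, FDR 6.61e-18). Apol10b rose from 5.26 to 66.04 RPKM, Uba7, the activating enzyme for ISG15, from 0.41 to 4.75 RPKM, and Igfbp5, an IGF binding protein, from 0.98 to 9.25 RPKM by the authors' values. The lowest log2 fold changes included Ctla2a (82.67 to 8.68 RPKM), Apol9b (6.94 to 0.59 RPKM) and Stra6, the receptor for retinol binding protein (6.96 to 1.19 RPKM), again from the authors' deposited table. Over all 23378 genes tested by the authors, 2811 were higher and 2448 lower at an FDR under 0.05. Both Fubp1 libraries and siNT A and B belong to one library set and siNT C to the other, and whether the authors' comparison allowed for this is not given in the sources used here.

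Splicing after Fubp1 knockdown changed mostly in cassette exons. Of 60137 tested events, 18 were higher and 58 lower in PSI at an adjusted p under 0.05 and a difference of at least 10 points, of which 65 were cassette exons (11 higher and 54 lower), 2 microexons of up to 27 nt, 6 introns and 3 alternative 3′ splice sites. Exons near full inclusion can only be called lower. Among called exons at 20 to 80% in siNT, a range chosen after the data were seen, 8 were higher and 15 lower (exact binomial test, two-sided, p 0.21), and 105 and 227 with binomial read weights (p 1.86e-11). This and the later binomial tests count exons as independent, although all come from the same libraries. Their p does not measure the spread between libraries. A 36 nt exon of Dock9, an exchange factor for Cdc42 (chromosome 14, 121959147 to 121959182 as the deposited table gives it), went from 67.3% ± 6.8 (SD, n = 3) in siNT to 5.8% ± 3.4 (SD, n = 2), with a limma adjusted p of 0.0214. In at least 1 library the Dock9 exon had fewer than 20 reads. An exon of Sbf2, a myotubularin-family protein, went from 44.2% ± 4.3 to 7.3% ± 2.8, and one of Cep170, a centrosomal protein, from 62.3% ± 5.0 to 26.7% ± 2.9. In the other direction, a 199 nt exon of Ppp1r9a, which encodes the actin-binding protein neurabin, went from 29.7% ± 7.1 to 82.9% ± 3.0 (limma adjusted p 0.0383), and a 135 nt exon of Ntrk3, the receptor for neurotrophin-3, from 44.9% ± 4.3 to 84.6% ± 1.3 (limma adjusted p 0.0349). Among genes of the preset list of splicing hosts, exons of Abi1 (96.8% ± 0.4 to 80.9% ± 2.8), Neo1 (95.5% ± 0.8 to 83.0% ± 1.0) and Ktn1 (84.4% ± 1.9 to 56.9% ± 0.9) fell. An intron of Fubp1 itself was retained at 4.2% ± 2.0 in siNT and 46.6% ± 6.3 after knockdown (limma adjusted p 0.0178).

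With binomial read weights limma called 856 events (237 higher and 619 lower). The fit without weights recovered few simulated changes, though few events were changed in that simulation. The authors' own calls, which mark no tested alternative splice site, covered 73 of the 76 events. With the term for the library sets 36 events were called (5 higher and 31 lower), and the 18 named events kept their direction and moved by up to 2.5 points, with 7 of them at an adjusted p under 0.05. Without Fubp1 library A or B the count was 1 each, and without any other single library it lay between 18 and 44.

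Transcription factors of the sympathetic neuron and adrenal lineage were lower after Khsrp knockdown. Of 17 tested, 5 fell and none rose (7 and 1 adjusted over the list alone, adjusted p 1.20e-06). The authors' deposited table gives Myt1, a zinc finger factor of neurogenesis, 40.79 RPKM in siNT and 15.69 RPKM after knockdown, Insm1, a factor of neuroendocrine differentiation, 38.98 and 21.96 RPKM, Gata2 61.72 and 23.99 RPKM, and Sox4 76.55 and 56.31 RPKM. Splicing regulators were lower in 6 of 82 and higher in none (the same count adjusted over the list alone, adjusted p 2.41e-04), including the neuronal regulator Ptbp2 (104.17 to 52.82 RPKM by the authors' values), Tia1 and Mbnl1. MYC targets were lower in 7 of 41 and higher in 1 (12 and 1 adjusted over the list alone, adjusted p 5.06e-04). Interferon-stimulated genes were higher in 3 of 40 and lower in none (4 adjusted over the list alone, adjusted p 5.22e-03). In the list of matrix and adhesion genes 10 of 39 fell and 2 rose (13 and 3 adjusted over the list alone, adjusted p 0.0126), with the integrins Itgb1 (334.48 to 142.01 RPKM in the authors' table) and Itga1 among those that fell. The stress list had 5 of 42 lower and none higher (8 adjusted over the list alone, adjusted p 5.42e-03). The neural progenitor list had 6 of 20 higher and 1 lower (6 and 2 adjusted over the list alone, adjusted p 0.0263). None of these lists passed with log2 fold changes as the statistic, where the adjusted p was 0.312 for the transcription factors, 0.481 for interferon-stimulated genes, 0.839 for matrix genes and 0.753 for the other 4. With ranks the matrix list (adjusted p 0.0806) and the progenitor list (0.0972) did not pass either.

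Among single genes after Khsrp knockdown, Ubb, a polyubiquitin gene, went from 960.44 to 157.54 RPKM in the authors' deposited table (log2 fold change -2.62, FDR 4.06e-61). Sptan1, the alpha chain of spectrin, went from 106.13 to 30.36 RPKM (-2.25), Nefh, the heavy neurofilament, from 25.34 to 7.28 RPKM (-1.92, FDR 3.51e-29) and the immediate early gene Egr1 from 10.99 to 2.99 RPKM by the authors' values. Myl9 rose to 54.91 RPKM (3.32, FDR 3.56e-92), the muscle LIM protein gene Pdlim3 from 20.21 to 142.4 RPKM (2.71) and the laminin chain Lamb2 from 1.07 to 6.58 RPKM in the same deposited table of the authors. In all, 893 genes were higher and 1015 lower at the authors' FDR under 0.05. Both Khsrp libraries lie in the later library set with siNT C, while siNT A and B lie in the other.

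For splicing, the limma fit without weights called 0 of 60137 events after Khsrp knockdown, with 5277 at an unadjusted p under 0.05. The fit with binomial read weights called 110 (29 higher and 81 lower), of which the authors' calls held 105, and their table marks 1119 of the tested events. The exons named here were taken from those 105 after their values were seen, and their adjusted p comes from the weighted limma fit. A 15 nt microexon of Eea1, a tether of early endosomes, went from 43.8% ± 8.2 (SD, n = 3) to 7.7% ± 4.1 (SD, n = 2, limma adjusted p 0.0228). A 12 nt microexon of Ank2, an ankyrin, went from 65.2% ± 2.3 to 35.8% ± 11.7 (0.0339) and a 9 nt microexon of Asap1, an Arf GTPase-activating protein, from 93.7% ± 1.7 to 79.8% ± 2.4 (0.0155). A 42 nt exon of the kinesin gene Kif1b went from 37.9% ± 0.3 to 19.3% ± 0.4 (3.75e-04), and a 42 nt exon of Numa1, a spindle pole protein, from 70.9% ± 1.1 to 42.0% ± 2.7 (2.26e-05). Higher inclusion was seen for exons of the translation factor Eif4h (45% ± 1.8 to 67.7% ± 0.4, 1.02e-05) and of tropomyosin Tpm1 (44.2% ± 2.8 to 66.4% ± 0.5, 9.22e-04). An intron of Khsrp itself was retained at 5.4% ± 3.8 in siNT and 44.2% ± 1.8 after knockdown (3.42e-03). With the term for the library sets the unweighted fit called 0 events and the weighted fit 24 (11 higher and 13 lower). The 16 named events kept their direction with that term and moved by up to 17.7 points, the most for an intron of Inha, with a median of 2.2 points.

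The double knockdown had the most changes in expression and in splicing of the 4 knockdowns. Interferon-stimulated genes were higher in 25 of 40 and lower in 3 (26 and 3 adjusted over the list alone, adjusted p 8.11e-09). They included Igtp (0.22 to 1.91 RPKM in the authors' deposited table), Ddx58, Psmb8 and Parp9. Transcription factors of the sympathoadrenal list were lower in 9 of 17 and higher in none (11 adjusted over the list alone, adjusted p 3.21e-07). Myt1 stood at 40.79 RPKM in siNT and 10.0 RPKM after knockdown by the authors' values, and Insm1 and Isl1 were also lower. Neuronal differentiation genes were lower in 17 of 36 and higher in 2 (the same counts adjusted over the list alone, adjusted p 3.73e-05). In the authors' table the secretory granule gene Chgb went from 248.21 to 92.81 RPKM and Celf4 from 12.76 to 2.39 RPKM, while Stmn4, a stathmin, went up from 22.76 to 104.07 RPKM. S phase genes were lower in 31 of 47 and higher in none (35 and 1 adjusted over the list alone, adjusted p 4.41e-13). Hells, a chromatin remodeler, stood at 116.07 and 22.41 RPKM in the authors' table. Splicing regulators were lower in 30 of 82 and higher in 1 (31 and 1 adjusted over the list alone, adjusted p 5.28e-07), among them Rbfox1 (4.54 to 0.59 RPKM by the authors' values), Ptbp2 and Elavl2. MYC targets were lower in 21 of 41 and higher in 1 (24 and 1 adjusted over the list alone, adjusted p 1.40e-06).

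Smaller shifts in the double knockdown concerned mesenchymal markers, 5 of 19 higher and 1 lower (adjusted p 1.74e-03), and p53 targets, 12 of 33 higher and 4 lower (0.0369). They also concerned G2 and M phase genes, 12 of 50 lower and 2 higher (0.0198), cholesterol genes, 9 of 25 lower and 2 higher (0.0140), and hypoxia genes, 14 of 34 lower and 3 higher (0.0391). Adjusted over the list alone these counts were 5 and 1, 12 and 4, 12 and 3, 9 and 2, and 15 and 5. The interferon and the sympathoadrenal lists passed with log2 fold changes as the statistic (adjusted p 9.92e-04 and 0.0295), and the other 9 named for this knockdown did not (adjusted p 0.101 to 0.753). Ranks gave 0.230 for mesenchymal markers, 0.132 for p53 targets and 0.0600 for hypoxia genes. Single genes with large changes included Myl9 (139.12 RPKM, log2 fold change 4.76, FDR 8.72e-177), smooth muscle actin Acta2 (3.89 to 60.93 RPKM), Ifitm3, an interferon-induced membrane protein (4.5 to 96.68 RPKM), and Timp3, an inhibitor of metalloproteinases (1.62 to 21.2 RPKM), in the authors' deposited table. Unc45b, a chaperone of muscle myosin, rose from 0.01 to 2.24 RPKM (7.43), and Dzip3 went from 60.65 to 3.75 RPKM (-3.82) by the authors' values. In all, 3080 genes were higher and 3192 lower at the authors' FDR under 0.05.

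Splicing in the double knockdown changed more often in microexons than in longer exons. Of 478 tested microexons, 8 were higher and 102 lower (23.01% called), against 526 higher and 2009 lower of 20841 longer cassette exons (12.16%), an odds ratio of 2.16 with a 95% interval of 1.72 to 2.69 (Fisher's exact test, two-sided, adjusted p 2.86e-10). Retained introns were called in 400 of 26596 cases (1.5%), an odds ratio of 0.110 against cassette exons (95% interval 0.0988 to 0.123). With the term for the library sets 78 introns were called (odds ratio 0.0408), and the odds ratio of microexons was 1.77 (adjusted p 8.14e-04). Events of 1 gene are not independent, which these tests do not allow for. Neither these nor the later class tests matched the classes on starting inclusion. A mean PSI of 10 to 90 was found for 213 of 478 microexons and 4560 of 20841 longer cassette exons. In all, 741 events were higher and 2427 lower, in 1790 genes, but exons near full inclusion can only be called lower, and 494 of 2645 called exons stood at 20 to 80% in siNT, a range chosen after the data were seen. Of these 215 were higher and 279 lower (56.5% lower, exact binomial test, two-sided, p 4.54e-03), 78 and 146 with the term for the library sets (p 6.50e-06), and 415 and 465 with binomial read weights (p 0.0985).

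A 21 nt microexon of the SUMO protease gene Senp6 (chromosome 9, 79946693 to 79946713 as the deposited table gives it) went from 93.2% ± 1.6 (SD, n = 3) in siNT to 9.5% ± 1.9 (SD, n = 2) in the double knockdown, with a limma adjusted p of 4.72e-05. In the single knockdowns it stood at 83.3% ± 0.5 for Fubp1 and 84.3% ± 5.6 for Khsrp. The 9 nt microexon of Asap1 went to 32.5% ± 3.7 and one of 9 nt in Ap1s2, a subunit of a clathrin adaptor, from 96.7% ± 0.8 to 48.8% ± 5.7 (limma adjusted p 1.89e-04 and 1.09e-04). Exons of Rasa1, a Ras GTPase-activating protein (99.5% ± 0.3 to 18.5% ± 4.4), of Hectd2 (95.3% ± 1.7 to 15.6% ± 2.3), and of Exoc5, a subunit of the exocyst (99% ± 0.7 to 22.2% ± 11), were also mostly skipped. Higher inclusion was found for exons of Ppp1r9a (90.2% ± 1.9), Eno4, an enolase (32.6% ± 13 to 87.0% ± 18.3), and the autophagy protease Atg4a (9.7% ± 1.4 to 60% ± 0.0). An alternative 3′ splice site of Gdi2, a regulator of Rab proteins, went from 6.9% ± 1.2 to 77.2% ± 1.3 (limma adjusted p 1.48e-04). An intron of R3hdm1 rose from 22.2% ± 7.8 to 88.9% ± 15.7, and one of Zwint, a kinetochore protein, fell from 75.9% ± 4.4 to 13.8% ± 7.1. The R3hdm1 intron had fewer than 20 reads in at least 1 library and did not have balanced junction reads in every library.

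With binomial read weights limma called 4782 events (1280 higher and 3502 lower). The authors marked 2976 of the 3168 events called without weights. Those 3168 include 65 alternative 3′ and 58 alternative 5′ splice sites, classes of which the authors' calls mark no tested event. With the term for the library sets 1570 were called (266 higher and 1304 lower), the 19 named events kept their direction and moved by up to 12.6 points, and 14 of them had an adjusted p under 0.05. Tcta, Ankrd32, Eno4, R3hdm1 and Synj1 did not (0.0590, 0.0654, 0.0955, 0.113 and 0.148). Without double knockdown library A or B the count was 1832 or 1678.

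**Figure D3:**
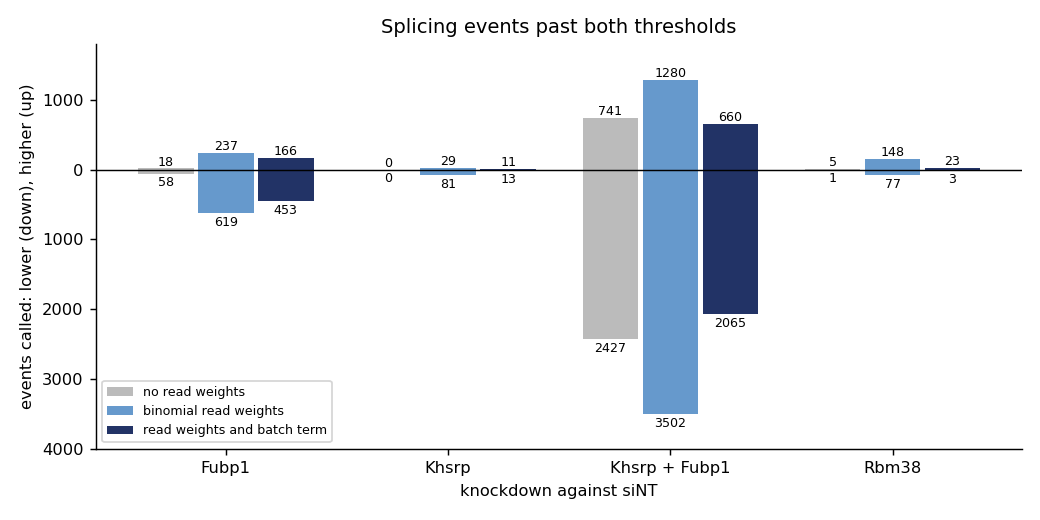
Bars count events called higher (up) and lower (down) in PSI for each knockdown against siNT in 3 limma fits: without weights, with binomial read weights, and with weights and a term for the library sets. Lower events outnumbered higher ones for Fubp1 (58 and 18 without weights) and the double knockdown (2427 and 741), and higher events outnumbered lower ones for Rbm38 with weights (148 and 77).

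The double knockdown was also set against each single knockdown. Against the Fubp1 knockdown 135 events were higher and 624 lower, and microexons were called more often than longer cassette exons (odds ratio 2.37, 95% interval 1.62 to 3.39, Fisher's exact test, adjusted p 2.89e-05, not tested with the term). An exon of Prpf4b, a kinase of the spliceosome, stood at 100.0% ± 0.0 in the Fubp1 knockdown and 19.9% ± 0.9 in the double knockdown (n = 2 each, limma adjusted p 0.0287), and the Senp6 microexon differed by -73.9 points (1.69e-03). The Prpf4b exon had fewer than 20 reads in at least 1 library. The Fubp1 and double knockdown groups lie in different library sets: with the term only 30 events were called, and Prpf4b and Senp6 had an adjusted p of 0.0456 each. Without Fubp1 library A or B, or double knockdown library A or B, the count of 759 went to 177, 212, 205 and 154. Against the Khsrp knockdown, which lies in the same set, 288 were higher and 1540 lower (1797 called with the term), with an odds ratio of 1.5 for microexons (95% interval 1.10 to 2.00, Fisher's exact test, adjusted p 0.0144). The count of 1828 went to 1053, 1091, 853 and 727 without Khsrp library A or B, or double knockdown library A or B. An intron of Vps13a, a lipid transfer protein, stood at 9.2% ± 3.3 in the Khsrp knockdown and 73.4% ± 15 in the double knockdown (limma adjusted p 4.76e-03). The Khsrp knockdown differed from the Fubp1 knockdown in 37 events, 25 higher and 12 lower, of which the term left 2, and which lay between 2 and 25 without any 1 library except siNT C (53). Among them an exon of the bicarbonate transporter Slc4a7 stood at 28.2% ± 7.2 in the Fubp1 and 87.4% ± 1.4 in the Khsrp knockdown (limma adjusted p 0.0420), or 44.1 points apart in place of 59.1 with the term (adjusted p 0.511). Expression in the double knockdown could not be tested against a single knockdown, since the authors' table holds no such comparison and no value per library.

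The interaction of both knockdowns, the double knockdown against the sum of both single effects on the log odds of inclusion, was called for 26 cassette exons, 1 above and 25 below the sum. A 132 nt exon of Pcm1, which organises centriolar satellites, stood at 95% ± 1.2 in siNT, 85.1% ± 1.4 and 95% ± 0.1 in the Fubp1 and Khsrp knockdowns, and 38.8% ± 4.9 in the double knockdown (limma adjusted p 0.0415). A 184 nt exon of Prkar1a, a regulatory subunit of protein kinase A, was the 1 exon above the sum, at 83.0% ± 1.6, 64.6% ± 0.7, 72.3% ± 0.5 and 81.5% ± 2.2 (limma adjusted p 0.0256). Of the 26 exons, 22 stood at 95% or more (a bound chosen after the data were seen) in siNT and in both single knockdowns, where log odds depend on the reads added and an exon can only be called below the sum. With binomial weights 278 events were called (56 above and 222 below the sum), of which 9 were among the 26, and with the term 12 were called. Without 1 library the count fell to between 5 and 19, lowest without Fubp1 library B or either double knockdown library.

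After Rbm38 knockdown interferon-stimulated genes were higher, and MYC targets, glycolysis and sterol genes were lower. Of 40 interferon-stimulated genes 21 were higher and 1 lower (27 and 1 adjusted over the list alone, adjusted p 4.77e-15), including the antiviral genes Rsad2 (0.14 to 0.89 RPKM in the authors' deposited table) and Ifit2 (0.77 to 2.63 RPKM). MYC targets were lower in 18 of 41 and higher in none (24 and 1 adjusted over the list alone, adjusted p 1.28e-11). Ncl, the gene of nucleolin, stood at 852.67 and 441.82 RPKM, and Cad, an enzyme of pyrimidine synthesis, at 68.48 and 34.58 RPKM by the authors' values. Hypoxia and glycolysis genes were lower in 12 of 34 and higher in none (17 adjusted over the list alone, adjusted p 7.12e-08). In the authors' table phosphofructokinase Pfkl went from 106.72 to 47.36 RPKM, pyruvate kinase Pkm from 950.39 to 573.93 RPKM and lactate dehydrogenase Ldha from 1584.22 to 1106.76 RPKM. Cholesterol genes were lower in 10 of 25 and higher in none (12 adjusted over the list alone, adjusted p 3.93e-06), with the isoprenoid enzyme Idi1 at 161.64 and 78.28 RPKM in the deposited table of the authors. Splicing regulators were lower in 24 of 82 and higher in 2 (26 and 3 adjusted over the list alone, adjusted p 5.28e-07), among them Srsf10, Hnrnpf and Elavl1. G2 and M phase genes were lower in 12 of 50 and higher in none (16 adjusted over the list alone, 4.13e-05). S phase genes were lower in 7 of 47 and higher in 1 (the same counts adjusted over the list alone, 3.14e-03).

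Of these lists only the interferon-stimulated genes passed with log2 fold changes as the statistic (adjusted p 3.89e-05), and the hypoxia list stood at 0.0640, MYC targets at 0.150 and the others between 0.333 and 0.718. Single genes with large changes included Slc16a3, an exporter of lactate (335.95 to 80.95 RPKM, log2 fold change -2.07), Dysf, the membrane repair protein dysferlin (7.43 to 1.98 RPKM, -2.34), and Slc22a18, an organic cation transporter (1.06 to 10.59 RPKM, 3.34), in the authors' deposited table. In all, 1860 genes were higher and 1640 lower at the authors' FDR under 0.05. Both Rbm38 libraries lie in the later library set with siNT C.

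After Rbm38 knockdown the limma fit without weights called 6 exons, 5 higher and 1 lower, too few for a direction to pass (exact binomial test, two-sided, adjusted p 0.292). A 9 nt microexon of Psap, the precursor of the saposins, rose (45.4% ± 0.8, SD, n = 3, to 66.0% ± 1.0, SD, n = 2, limma adjusted p 0.0110). So did exons of the dynein chain Dync1i2 (30.6% ± 1.8 to 56.5% ± 4.9, 0.0493), Eif4h (45% ± 1.8 to 65.6% ± 2.3, 0.0457), Pxdn (84.4% ± 0.5 to 94.9% ± 0.8, 0.0493) and Mgea5, the gene of O-GlcNAcase (87.1% ± 2.3 to 97.6% ± 0.1, 0.0457). An exon of Rnf167, a ubiquitin ligase, fell from 100.0% ± 0.0 to 87.3% ± 3.7 (0.0151). With binomial weights 225 events were called (148 higher and 77 lower), 209 of them also called by the authors. From these, and after the values were seen, come a 6 nt microexon of Pacsin2 (34.6% ± 3.6 to 62.8% ± 6.6, weighted limma adjusted p 1.51e-03) and the 42 nt exon of Kif1b (37.9% ± 0.3 to 56.0% ± 2.1, 1.71e-04). So do a 711 nt exon of the tau gene Mapt (9.6% ± 1.9 to 28.5% ± 1.4, 3.80e-05) and an exon of the GABA receptor gene Gabbr1 (52.2% ± 7.1 to 86.1% ± 2.4, 1.92e-04). Exons of Nrxn2, a neurexin (75% ± 8.6 to 38.2% ± 8.8, 0.0221), and Ddb2, a DNA damage sensor (60.1% ± 6.5 to 23.9% ± 9.5, 0.0461), were lower. The Ddb2 exon had fewer than 20 reads in at least 1 library. With the term for the library sets 0 events were called without weights and 26 with weights (23 higher and 3 lower). The 6 called events kept their direction with it and moved by up to 2.4 points, and all were lost from the call (adjusted p 0.101 to 0.248). The 17 events named from the weighted and the authors' calls kept their direction and moved by up to 13.8 points, with a median of 4.3 points. Without siNT C 6 events were called, without either Khsrp library, either double knockdown library or Rbm38 library A 2, and without any of the other 5 libraries 0.

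**Figure D4:**
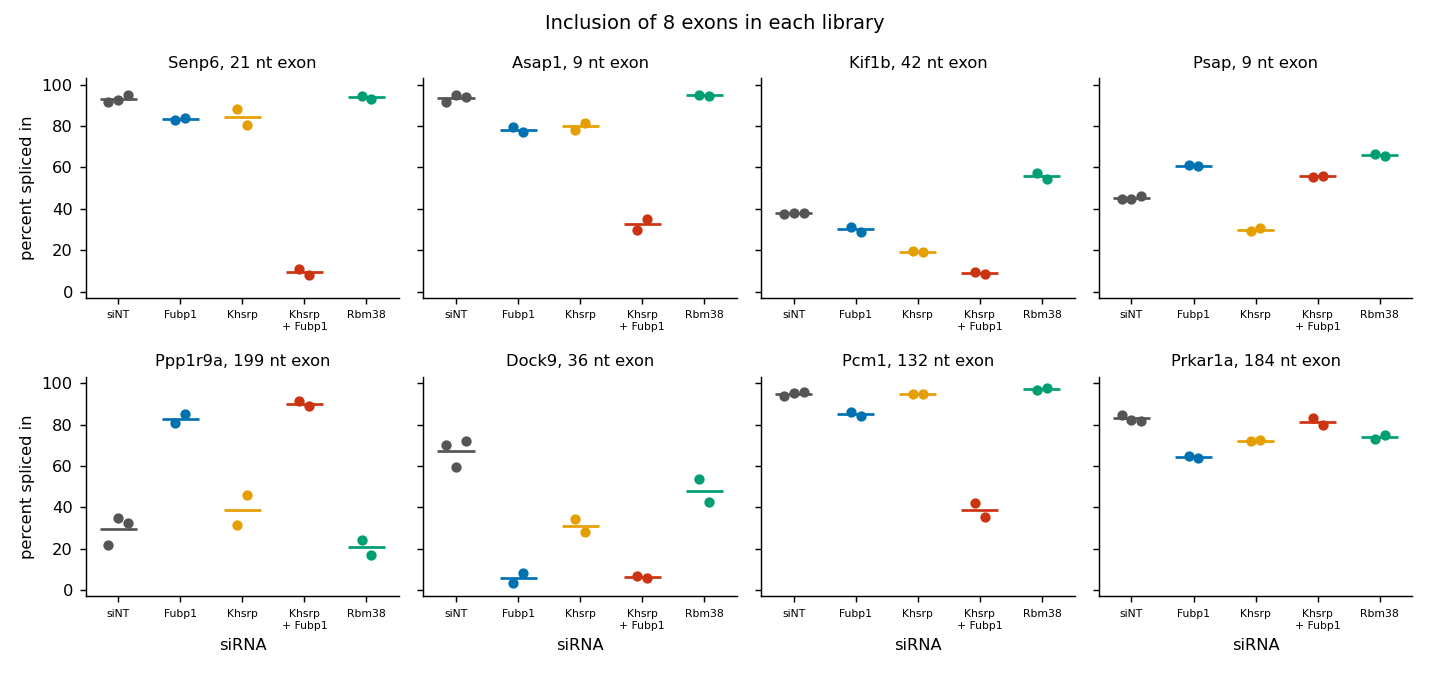
Points give PSI (percent, vertical axis) of 8 named exons in each of the 11 libraries by group, with a line at each group mean. The Senp6 microexon lies at 93.2% in siNT and 9.5% in the double knockdown, and the Psap microexon at 45.4% in siNT and 66.0% in the Rbm38 knockdown.

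Several gene lists gave no call in the test set out beforehand. Targets of let-7, whose maturation Khsrp protein promotes, were higher in 5 of 31 and lower in 2 after Khsrp knockdown (5 and 5 adjusted over the list alone, adjusted p 0.613), and did not pass in the other knockdowns (0.0758 to 0.865). Immediate early and AU-rich element mRNAs, a class that Khsrp protein destabilises, were higher in 2 of 47 and lower in 4 after Khsrp knockdown (3 and 5 adjusted over the list alone, adjusted p 0.0622), with the authors' log2 fold changes of -2.04 for Egr1 and 1.04 for Btg2. The same test gave 0.291, 0.423 and 0.946 for Fubp1, double and Rbm38. With ranks the list passed for Khsrp alone (adjusted p 0.0341). Targets of p53 gave 6 higher and 6 lower of 33 after Fubp1 knockdown (0.893), 4 and 2 after Khsrp (0.858), and 6 and 3 after Rbm38 knockdown (0.765). Axon guidance genes outside the Fubp1 knockdown gave 0.167, 0.0701 and 0.799 for Khsrp, double and Rbm38. Matrix genes outside the Khsrp knockdown gave 0.270, 0.830 and 0.529 for Fubp1, double and Rbm38. The stress list, lower after Fubp1 knockdown, had 7 of 42 higher and 8 lower in the double knockdown (adjusted p 0.534), where Fubp1 itself stood lower still, and 5 and 6 after Rbm38 knockdown (0.925). S phase, G2 and M phase, cholesterol and hypoxia genes gave 0.649, 0.138, 0.695 and 0.994 after Khsrp knockdown. The sympathoadrenal list gave 0.893 and 0.857 for Fubp1 and Rbm38, and mesenchymal markers 0.262, 0.523 and 0.765 for Fubp1, Khsrp and Rbm38. Neuronal differentiation genes gave 0.0758, 0.0585 and 0.167 for Fubp1, Khsrp and Rbm38, and passed for Fubp1 with ranks (0.0204). Neural progenitor genes gave 0.925, 0.143 and 0.603 for Fubp1, double and Rbm38. Markers of 4 further cell types did not pass in any knockdown. They were astrocyte markers (10 tested, adjusted p 0.708 to 0.994), oligodendrocyte and Schwann cell markers (9 tested, 0.603 to 0.925), microglia and leukocyte markers (9 tested, 0.857 to 0.994) and endothelial markers (10 tested, 0.0862 to 0.967). The list of the targets and their paralogs passed in all 4 knockdowns (adjusted p 1.40e-06 to 0.0366). It holds the targeted genes themselves and was not tested without them. Of its 4 tested members 1 was lower after Fubp1 and after Khsrp knockdown, and 2 after double and after Rbm38 knockdown. Adjusted over the list alone, all 4 were lower after Rbm38 knockdown. With ranks the list passed after double (adjusted p 0.0488) and Rbm38 knockdown (9.35e-03), but not after Fubp1 (0.926) and Khsrp knockdown (0.861). It did not pass with log2 fold changes (0.150 to 0.753).

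Relative to all other tested events, microexons as a set were lower after Khsrp and double knockdown and higher after Rbm38 knockdown, in tests chosen after the data had been seen. After Fubp1 knockdown microexons were lower too, but not relative to the other events. The exons averaged here were those with a mean PSI of 10 to 90 over all 11 libraries, knockdowns included. Exons that moved strongly in a knockdown could enter through that move. Differences between these means are therefore partly set by the choice. Over the 213 such microexons, the mean was 50.8% ± 0.51 in siNT (SD, n = 3), 44.8% ± 0.83 after Khsrp, 35.5% ± 1.20 after double, 46.4% ± 0.92 after Fubp1 and 57.8% ± 1.03 after Rbm38 knockdown (SD, n = 2 each). The siNT libraries A, B and C stood at 51.3%, 50.3% and 50.7%, so that both library sets gave a like control level. The 4560 longer cassette exons moved less, from 59.8% ± 0.45 in siNT to 59.6% ± 0.28, 55.5% ± 0.03, 57.9% ± 0.47 and 60.4% ± 0.90 in the same order. Of all 478 microexons, 16 were higher and 78 lower at an unadjusted p under 0.05 after Khsrp, 33 and 179 after double, 33 and 66 after Fubp1, and 99 and 9 after Rbm38 knockdown. Against all other events, cameraPR from limma gave an adjusted p of 2.60e-04 for Khsrp, 3.58e-04 for double, 0.714 for Fubp1 and 2.34e-12 for Rbm38, and with the term for the library sets 0.0131, 4.21e-03, 0.475 and 2.04e-10. The authors' calls list 6 higher and 57 lower microexons for Khsrp, 22 and 145 for double, 27 and 61 for Fubp1, and 87 and 0 for Rbm38. The rise after Rbm38 knockdown was largest in microexons, with a median PSI change of 1.95 points. It was 0.30 points for cassette exons of 28 to 60 nt and 0.13 for those of over 60 nt. With the term for the library sets these medians were 1.77, 0.20 and 0 points. More of the longer exons were higher than lower too, but cameraPR sets them against all other events, among them introns that were lower. Cassette exons of 28 to 60 nt had 225 higher and 63 lower (adjusted p 0.0125 with cameraPR, 8.99e-03 with the term), and those of over 60 nt 1381 and 734 (0.0392 and 4.21e-03). With ranks in cameraPR the set of over 60 nt had an adjusted p of 0.0579, and 3.61e-03 with the term. Retained introns went the other way, with 537 higher and 1562 lower at an unadjusted p under 0.05 (adjusted p 3.50e-03 with cameraPR, 9.81e-05 with the term).

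**Figure D5:**
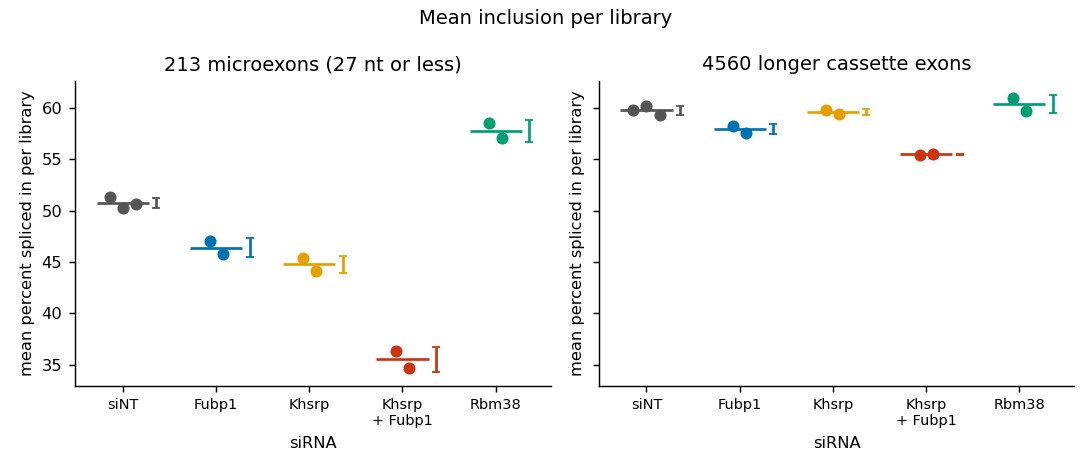
Points give the mean PSI (percent, vertical axis) of 213 microexons and of 4560 longer cassette exons in each of the 11 libraries, by group, with the group mean and SD. Microexons stood at 50.8% in siNT, 35.5% in the double knockdown and 57.8% in the Rbm38 knockdown, and the longer exons between 55.5% and 60.4% in all 5 groups.

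The knockdowns shared changes to different degrees. Of the 76 events called for Fubp1, 16 were called higher and 50 lower in the double knockdown too, against 0.22 and 2.34 expected for independent calls. With weights, Khsrp and the double knockdown shared 17 higher and 64 lower events, against 0.62 and 4.72. The covariance of effects on the log odds of inclusion across events was 0.959 for Fubp1 and the double knockdown and 0.641 for Khsrp and the double knockdown, above the 0.262 and 0.264 simulated for unchanged groups that share 3 controls. It was 0.239 for Fubp1 and Rbm38 (0.263 simulated). Khsrp and the double knockdown also share a library set, which the simulation leaves out, and no covariance is given with the term for the sets. The correlation was 0.562 for Fubp1 and the double knockdown (0.401 simulated). For Khsrp and the double knockdown it was 0.399 (0.404 simulated), so by this measure it did not exceed the shared-control value. The term for the library sets changes which controls are shared, and with it these correlations were 0.368 (-0.004 simulated with the term) and 0.519 (0.667 simulated with the term). For Fubp1 and Rbm38 the correlation went from 0.230 (0.402 simulated) to -0.024 (0.002 simulated). Fubp1 and Khsrp had a covariance of 0.343 (0.264 simulated) and a correlation of 0.327 (0.404 simulated), or 0.062 with the term (0.002 simulated). For the double knockdown and Rbm38 the covariance was 0.284 (0.263 simulated) and the correlation 0.178 (0.401 simulated), or 0.359 with the term (0.664 simulated). Khsrp and Rbm38 had a covariance of 0.373 (0.266 simulated) and a correlation of 0.380 (0.406 simulated), while with the term the correlation was 0.597 (0.665 simulated). Of 270 events in the authors' calls for both, 185 went the same way and 85 opposite ways. In the authors' expression calls, Fubp1 and the double knockdown shared 1405 higher and 1399 lower genes (370.5 and 334.4 expected for independent calls), Khsrp and double 585 and 696 (117.7 and 138.6), and Khsrp and Rbm38 333 and 272 (71.1 and 71.2). Fubp1 and Khsrp shared 314 and 301 (107.4 and 106.3), Fubp1 and Rbm38 557 and 452 (223.7 and 171.7), and double and Rbm38 704 and 665 (245.1 and 223.9). Shared controls raise these counts as well. The covariance of log2 fold changes was 0.344 for Fubp1 and double (0.111 simulated for shared controls), 0.321 for Khsrp and double (0.081), 0.226 for double and Rbm38 (0.093) and 0.190 for Khsrp and Rbm38 (0.105). For Fubp1 and Khsrp it was 0.056 (0.09) and for Fubp1 and Rbm38 0.063 (0.102), and did not exceed the simulated value. All these measures correlate genes or events, which are not independent replicates. The simulated values cover shared controls but leave out the library sets. Khsrp, double and Rbm38 lie in the later set while siNT A and B lie in the other, which may add to their covariances. For expression this could not be adjusted. The pairs of Fubp1 with Khsrp and with Rbm38 cross the sets, but so does the pair of Fubp1 and double, which exceeded the simulated value.

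Genes with a changed event more often had a changed level. In the double knockdown 874 genes had both, and 54.5% of genes with a called event were called for expression by the authors against 40.4% of the rest (odds ratio 1.77, 95% interval 1.58 to 1.98, Fisher's exact test, two-sided, adjusted p 7.52e-24). For Fubp1 it was 34 genes and 55.7% against 38.1% (odds ratio 2.05, 95% interval 1.20 to 3.54, Fisher's exact test, adjusted p 0.0108), which did not pass with events of at least 15 points (odds ratio 1.70, adjusted p 0.17). For Rbm38 it was 3 genes (adjusted p 0.216), and Khsrp had no called event to test. Genes were not matched on level, read depth or number of tested events, so these odds ratios are not adjusted for them.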

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

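The exons in this part come from a planned interaction test, while the tests of library sets and of depth, the range of 20 to 80% and the count of exons at 95% or more were chosen after the result had been seen. In 26 cassette exons the double knockdown differed from the sum of both single knockdowns, by an interaction term in limma. The exon of Prkar1a stood 27.5 points above the sum of the single effects, and the other 25 stood below it, which for most was the only way they could be called, among them exons of Pcm1 by -46.3 points, Strbp, which encodes an RNA-binding protein of spermatids, by -35.2 points, and Erbb2ip, which encodes the scaffold erbin, by -29.5 points. Inclusion of the Strbp exon was 100.0%, 99.5%, 100.0% and 64.3% in siNT, Fubp1, Khsrp and double knockdown, and that of the Erbb2ip exon 99.3%, 99.8%, 100.0% and 71.0%. Both are among 22 of the 26 exons that stood at 95% or more in 3 of the groups, where the log odds depend on the reads added. With binomial weights 9 of the 26 kept the call, while Strbp and Erbb2ip lost it (adjusted p 0.315 and 0.0504). Pcm1 and Prkar1a passed with weights (8.44e-04 and 3.69e-04), and with the term for library sets Prkar1a, Strbp, Pcm1 and Erbb2ip had an adjusted p of 0.0315, 0.0295, 0.0556 and 0.0556.

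Lower exon inclusion in the double knockdown was weighed against library sets and depth. Of 3168 called events 76.6% were lower, but exons near full inclusion can only be called lower, and among called exons at 20 to 80% in siNT the share was 56.5%. With the term for library sets that share was 65.2% of 224 exons, and with at least 50 reads in every library 56.8% of 474. By these shares neither the library sets nor the shallow double knockdown libraries are excluded as a contribution to the direction. Within the later library set, however, the 4560 longer cassette exons with a mean PSI of 10 to 90 averaged 55.44% and 55.48% in the double knockdown libraries. They averaged 59.29% in siNT C, 59.75% and 59.35% in the Khsrp libraries, and 60.99% and 59.72% in the Rbm38 libraries. These exons were chosen by their mean over all 11 libraries, the double knockdown included. Exons near full inclusion elsewhere could thus enter because they fell in the double knockdown. That choice favours a lower mean in the double knockdown, so these means do not settle the part of the library sets. With the term 1436 of the 3168 events kept the call. What also stays open is a plain sum of both single effects, from which 26 events departed without and 278 with binomial weights (no recovery of simulated departures was tested), a joint action of both proteins, or a response to transfecting 2 pools, since no group with 1 target pool and a second control pool is among the samples.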

How the results depend on the processing

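Chosen only after the data were seen were the tests with the term for library sets, with it and weights together, with balanced introns, with a 1 RPKM filter and with other list statistics; the rest were planned. No named gene, named event or count of all called events turned from the direction in the report under the alternatives run for it, but the list of targets after Fubp1 knockdown turned from lower to higher with ranks (adjusted p 0.926), and the excess of lower genes after Khsrp and double knockdown turned with a fold-change threshold. Microexons called for Fubp1 went from 2 higher and 0 lower to 15 higher and 37 lower with binomial weights. For Khsrp, with 0 called in the report, weights gave 29 higher and 81 lower, and leaving out siNT C gave 2 higher and 0 lower. Counts are given in the order Fubp1, Khsrp, double and Rbm38 knockdown against siNT (76, 0, 3168 and 6 in the report), double against Fubp1 (759), double against Khsrp (1828), interaction (26) and Khsrp against Fubp1 (37), and for each setting only counts that moved by over 1.5 times; the cause was not tested unless stated.

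Binomial weights gave 856, 110, 4782, 225, 2920, 3214, 278 and 644 events, odds ratios of 3.97 for Fubp1 microexons and 0.607 for the direction of Fubp1 exons against introns, both past the threshold with weights alone, though exons near full inclusion can only be called lower. The term for library sets gave 36 for Fubp1, 1570 for double, 0 for Rbm38, 30 for double against Fubp1, 12 for the interaction and 2 for Khsrp against Fubp1, with 1 control library left beside each later knockdown. The term with weights gave 619, 24, 26 (Rbm38), 344, 3459, 223 and 68 (all but double against siNT). Adjusted p alone gave 235, 6295 (double), 25 (Rbm38), 1305, 3319, 40 and 113, since it drops a criterion. With 15 points Rbm38 gave 3 and Khsrp against Fubp1 24, the overlap of Fubp1 and double events 10 higher and 33 lower, and the odds ratio of Fubp1 expression and splicing 1.70, no longer past the threshold. A minimum of 50 reads gave 3 for Khsrp and 40 for the interaction, and the coverage score 3 for Khsrp. Adding 2 to reads gave 183 for Fubp1, 1762 for double against Fubp1, 86 for the interaction and 107 for Khsrp against Fubp1. Without the PSI filter the counts were 1 for Fubp1, 0 for Rbm38, 340, 1107, 3 and 3 for the last 4 comparisons. With only the groups compared, and so fewer libraries to estimate the spread, they were 0 for Fubp1 and Rbm38, 372 and 929 for double against Fubp1 and Khsrp, and 0 for Khsrp against Fubp1. With the replicate letter as a term, 14 events were called for Fubp1, 1 for Rbm38, 3 for the interaction and 15 for Khsrp against Fubp1. A minimum of 20 reads and balanced introns moved no count by that much.

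Leaving out each library gave 1 to 44 events for Fubp1 (1 without Fubp1 A or B), 0 to 2 for Khsrp, 1678 to 3052 for double (1678 without double B, 1832 without double A), 0 to 6 for Rbm38, 154 to 780 for double against Fubp1 (154 without double B), 727 to 1796 for double against Khsrp (727 without double B), 5 to 19 for the interaction (19 without Rbm38 B) and 2 to 53 for Khsrp against Fubp1 (2 without Fubp1 B, 53 without siNT C). A lone library left in a group is assumed to vary like the other groups.

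With an absolute log2 fold change of at least 1 the authors' calls numbered 1747, 528, 2640 and 1031 genes (1056 higher and 691 lower, 276 and 252, 1427 and 1213, and 782 and 249). Shared genes, higher and lower, were 80 and 62 for Fubp1 and Khsrp, 513 and 319 for Fubp1 and double, 149 and 29 for Fubp1 and Rbm38, 164 and 136 for Khsrp and double, 89 and 15 for Khsrp and Rbm38, and 229 and 51 for double and Rbm38, all by a stricter criterion. Khsrp in the Rbm38 knockdown (-0.70) is then not called. For 98 named event results, each counted once per setting that still tested it, the call was the same in 1536 cases under the settings set out beforehand, lost in 431 and gained in 36, and in 223, 46 and 11 under those added later. Of the 98, a minimum of 20 reads left 88, 50 reads 70, the coverage score 81 and balanced introns 84. Events that dropped out of a setting are not counted as lost. For 34 list results, each tested with 2 other statistics, the call held in 35 cases and was lost in 33, of which 27 with log2 fold changes. A filter at 1 or 5 RPKM moved no named gene.

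Not run, for lack of values per library, were other normalizations, filters on counts, pseudocounts, other expression tests, the replicate term and left-out libraries for expression, the estimated correlation for lists, and edgeR on inclusion and exclusion reads. At the same simulated depth, with 100 changes of each size among 60137 events, the unweighted fit recovered 5 to 10 and the weighted fit 84 to 91 of 100 changes of 30 points. So few events changed in that simulation that it does not give the recovery in the real data. In the double knockdown the unweighted fit called 3168 and the weighted fit 4782 events.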

Other observations

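In this part the tests of interferon-stimulated genes against the control level and of the targets' own introns were chosen after the results had been seen, while the bound for introns of other genes that fell was written before its values. Some genes differed from siNT in several knockdowns. In the authors' deposited table Pdlim3 went from 20.21 RPKM in siNT to 83.33, 142.4, 128.66 and 98.18 RPKM in the Fubp1, Khsrp, double and Rbm38 knockdown, with an FDR from 5.91e-70 to 1.97e-42. Myl9 stood at 42.29, 54.91, 139.12 and 8.03 RPKM in the same order against 4.71 RPKM in siNT, and Acta2 at 22.93, 9.01, 60.93 and 4.12 RPKM against 3.89 RPKM, by the authors' values, where the Rbm38 knockdown did not pass their test for Acta2 (FDR 0.891). Sgpp2, a sphingosine phosphate phosphatase, was lower in all 4 knockdowns, from 6.63 RPKM in siNT to 1.07, 2.30, 0.61 and 1.46 RPKM in the authors' table. Slc22a18 was higher in all 4, at 3.17, 2.17, 4.54 and 10.59 RPKM against 1.06 RPKM, again by the authors' values. Each of these compares with the same 3 siNT libraries.

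Some exons stood below siNT after Khsrp knockdown and above it after Rbm38 knockdown, and the authors' calls mark the 4 given here in both. The 42 nt exon of Kif1b stood at 37.9% ± 0.3 in siNT (SD, n = 3), 19.3% ± 0.4 after Khsrp, 9.0% ± 0.5 after double and 56.0% ± 2.1 after Rbm38 knockdown (SD, n = 2 each). The exon of Prune2 stood at 19.4%, 8.7%, 1.5% and 51.1%, that of Ubr4 at 28.5%, 10.1%, 5.6% and 58.8%, and that of Dync1i2 at 30.6%, 19.8%, 5.1% and 56.5% in the same order. These 4 were picked for their opposite directions, while of 270 events in the authors' calls for both knockdowns 185 went the same way and 85 opposite ways. The difference between the Khsrp and Rbm38 knockdowns was not tested.

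Interferon-stimulated genes had a median log2 fold change in the authors' table of 0.55, 0.16, 1.10 and 0.91 in the Fubp1, Khsrp, double and Rbm38 knockdown. A low level in the 3 shared control libraries would raise all 4 alike, but 85% of the list's members were lower in the Khsrp than in the Rbm38 knockdown, which lie in the same library set. That argues against the control level as the whole cause. A response to particular siRNA pools, or to loss of the targets, may account for it, and both stay open because each target was reached with 1 pool.

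Introns of the targeted genes stood higher in the single knockdown of that gene, and less so for Fubp1 in the double knockdown, but of these only 1 of Fubp1 passed as a call in the single knockdowns and 2 each of Fubp1 and Khsrp in the double. All 5 tested introns of Fubp1 (100%) were higher after Fubp1 knockdown, by a median of 7.4 points, all 11 of Khsrp after Khsrp knockdown, by 5.8 points, and both of Rbm38 after Rbm38 knockdown, by 9.4 points, against medians of -0.8 to 0.1 in single knockdowns of another gene. In the double knockdown 10 of 11 Khsrp introns were higher, by a median of 5.1 points, but 4 of 5 Fubp1 introns by 1.3 points (lowest -2.4), although Fubp1 stood lower there (19.82 against 27.89 RPKM in the authors' table). Loss of spliced mRNA in the cytoplasm while unspliced RNA is left may account for the single knockdowns, but the Fubp1 introns of the double knockdown leave it open, and it was not measured here. A fall in level by itself is a less likely cause of rises of this size, since 60 introns of 31 other genes with a log2 fold change of -1.5 or lower changed by a median of 0.55 points after Fubp1 knockdown, and such introns by 0.72, 1.16 and 2.1 points after Khsrp, double and Rbm38 knockdown. For Rbm38 that median passed the 2 points set beforehand, with 26 introns, so the Rbm38 introns stay open. A small link with level was present in all 4 knockdowns. In the order Fubp1, Khsrp, double and Rbm38, all introns had medians of -0.40, -0.22, -0.70 and -0.41 points. Introns of genes that rose had medians of -1.24, -1.11, -2.21 and -0.66 points. The targets fell further than the bound, with log2 fold changes of -2.60, -2.77 and -3.42 for Fubp1, Khsrp and Rbm38 in their single knockdowns.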
